A study of Rattus norvegicus with 64 samples.

How the data were processed

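The series holds RNA-seq of liver and kidney from Sprague Dawley rats that received bromobenzene (0.4 g/kg) or saline vehicle and were sampled after 5 h or 10 h. Each tissue, time and agent has 8 libraries, 64 in all, from 32 rats per the series description. Groups were taken from the tissue, time and agent labels. The labels do not give sex or age, and they do not say which liver and kidney libraries came from the same rat. Replicate numbers follow the order of the records within a group, so a liver and a kidney library of one number, time and agent are library n and library n + 32, a pairing the labels do not state and the tests did not use except in alternatives and observations. Per the labels' protocols, polyadenylated RNA was made into stranded libraries and sequenced as 150-nt read pairs. The protocol text speaks of cultured cells although the tissue labels name liver and kidney, and the tissue labels were used here.

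Per the submitters' processing notes, reads were quantified with kallisto 0.42.4, and the build named is Rnor_6.0. Each deposited table lists 31715 transcripts with their length, effective length, estimated count and TPM, in the same order in all 64 libraries. The estimated counts were deposited by the authors as kallisto gives them, unnormalized and not whole, because reads shared by several transcripts are divided among them. The TPM values were deposited beside them, scaled to a fixed sum per library and corrected for effective length. The annotation release, read trimming and any filters are not given in the sources used here. Because kallisto divides shared reads, levels of isoforms of one gene, of near-identical paralogs and of pseudogenes are uncertain.

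The tables identify features by Ensembl transcript IDs with no gene IDs or symbols, and the files do not pair them with names. The reference table used here (assembly GRCr8) carries no Ensembl IDs, so 0 transcripts were matched to a gene. The tests were therefore run on transcripts in place of sums per gene, the lists of named genes fixed before the data were examined were not tested, and no coordinates are given. The rule for named features asked for a mean CPM (counts per mega-count of the library, SI prefix, computed here) of at least 5 in the tissue, an adjusted p under 0.05, at least 7 of the 8 bromobenzene libraries on the same side of the vehicle median, and a gene symbol. Without symbols, 1561 liver and 113 kidney transcripts met the other conditions at 10 h. The one with the largest rise and the one with the largest fall in each tissue at 10 h are named by ID, as a restriction of that rule made after the files were seen.

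Estimated counts were rounded to whole numbers. Transcripts were kept with edgeR's filterByExpr (minimum count 10, minimum total 15), scaled by TMM, and tested with edgeR 4.0.16 in R 4.3.3 (robust estimateDisp and glmQLFit, glmQLFTest). The 4 groups of a tissue shared one fit of 32 libraries with no covariate. Its contrasts were bromobenzene against vehicle at each time, the difference between those, and vehicle at 10 h against 5 h. The organs were compared at each time in a fit of 32 libraries over transcripts with a mean CPM of at least 1 in each tissue, by the difference between the liver and kidney responses. A transcript was called at a Benjamini-Hochberg adjusted p under 0.05, and adjusted p-values given for transcripts come from these edgeR tests.

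In place of gene lists, groups of transcripts were defined from other libraries than those compared, a choice made after the files were seen. Liver-enriched and kidney-enriched transcripts were at least 16-fold higher in one tissue than in the other on the mean of log2(CPM + 0.5), with a level of at least 5 CPM, in the vehicle libraries of the other time. For the difference between the times they had to meet this at both times, so that definition is not independent of the contrast. The other groups were transcripts called in the other tissue at the same time and transcripts called in the same tissue at the other time. Lists from the other tissue come from organs of the same rats and are not independent of the comparison tested. They were tested with limma 3.58.1's camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, which asks whether members move one way on balance. A response score was computed per library as the mean log2 CPM of the transcripts that rose at the other time minus that of those that fell, set against the vehicle mean of its own time. Scores, shares of counts and depth were compared by two-sided exact permutation tests over all 12870 splits of 16 libraries.

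In mega-counts of estimated counts, totals ranged from 13.8 to 28.3 per liver library and from 16.98 to 24.1 per kidney library. Read counts without molecular identifiers are not counts of independent molecules. None of 224 pairs of libraries within a group came near sampling noise (lowest chi-square per degree of freedom 10.3), so each counted once. In simulated counts with known changes, the test recovered 57.5% of 1.5-fold, 93.8% of 2-fold and 100% of 4-fold changes at 10 h in liver, with 7 false calls among 168. For kidney at 10 h it recovered 78.8%, 93.8% and 95% at those sizes, with 7 false calls among 183. The difference between the times was recovered less often, at 41.2%, 67.5% and 90% in liver (6.8% of calls false) and 60%, 83.8% and 92.5% in kidney (5.6% false). These false shares lay above 5%, but each was simulated once, so they do not settle whether the test exceeds that rate. The difference between organs was recovered at 42.5%, 75% and 90% at 5 h (3% false) and 35%, 77.5% and 82.5% at 10 h (4.7% false). Changes were simulated only in transcripts above a minimum mean count, so recovery among scarcer ones was not measured. The list tests were tested on simulated lists of 100 transcripts. A list raised 1.3-fold at 10 h gave a camera p of 1.5e-74 in simulated liver, and an unchanged list gave 0.803. Simulated transcripts were drawn independently, so this does not test the list tests where members are correlated. In the data the estimated correlation was 0.44 for liver-enriched transcripts in kidney at 5 h, far above the preset 0.01.

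Library numbers in the labels follow the groups one after another for numbers 1 to 18 and 33 to 50, here the first run, and mix them for 19 to 32 and 51 to 64, the second run. The labels name no batch. In kidney, 15 of 18 libraries of the first run and 1 of 14 of the second lay above the median of the leading principal component, and 1771 kidney transcripts differed between the runs, against 81 in liver. Libraries also differed in a trend of level with transcript length, whose rank correlation with the leading component of liver was 0.94 in size. Both were used as covariates in alternatives added after the data were examined.

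Alternatives fixed before the data were examined were DESeq2 1.42.0, RLE factors, library totals alone, no filter on low counts, a mean CPM of at least 5, an offset for effective length, limma on log2(TPM + 1) and log2(TPM + 0.1), only the groups compared, a 1.5-fold minimum change, an adjusted p under 0.01, removal of the 20 most abundant transcripts, voom with sample weights, and assumed rat pairs for the organ comparison. The assumed rat pairs were fitted with voom and limma in place of edgeR. Added after the data were examined were each library left out in turn, the run and length covariates, each run alone, and removal of libraries that stood apart.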

Results

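Transcript levels were measured in liver and kidney of Sprague Dawley rats, an outbred laboratory stock, after bromobenzene or saline. Bromobenzene is an aromatic solvent used as a model liver toxicant. Liver cytochrome P450 enzymes oxidize it to reactive products that bind glutathione, and its metabolites also reach the kidney. Rats received 0.4 g/kg and were sampled at 5 h or 10 h, with 8 bromobenzene and 8 vehicle libraries per tissue and time. Mean depth in liver, in mega-counts (SI prefix) of estimated counts, was 24.5 (SD 2.69, n = 8) after bromobenzene and 22.6 (SD 2.85) after vehicle at 5 h, and 22.2 (SD 4.83) and 21.99 (SD 2.38) at 10 h. In kidney it was 18.99 (SD 1.31) and 21.1 (SD 1.96) at 5 h, and 20.7 (SD 2.05) and 19.9 (SD 1.64) at 10 h. Bromobenzene kidneys at 5 h had less depth than vehicle kidneys (exact permutation p = 0.0255), and the other differences did not pass (exact permutation p = 0.179 and 0.928 in liver at 5 h and 10 h, and 0.393 in kidney at 10 h). The tables do not pair transcripts with gene names, so 4 transcripts are given by ID and the others as groups.

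**Figure D1:**
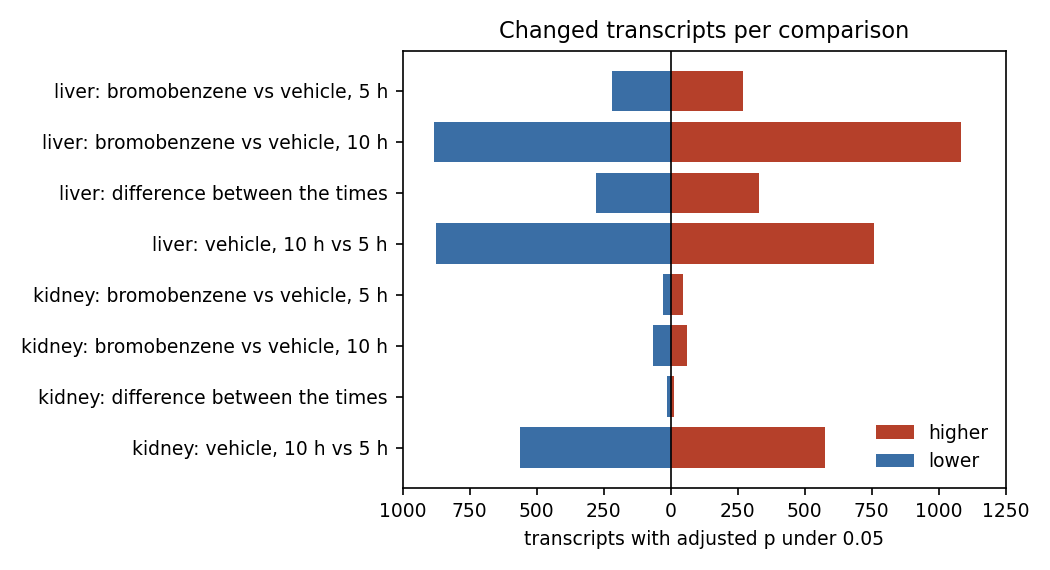
Number of transcripts with an edgeR adjusted p under 0.05 in each comparison, higher to the right of 0 and lower to the left (horizontal axis, transcripts; 8 libraries per group). Liver at 10 h had 1967 changed transcripts and kidney at 10 h had 125.

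The first comparison asked what bromobenzene changed in liver after 5 h. Of 17535 transcripts tested, 269 rose and 219 fell in bromobenzene liver. The risers changed by a median of 1.71-fold, 92 of them at least 2-fold, and the fallers by 1.46-fold, 34 of them at least 2-fold. The risers made up 2.38% ± 0.268 (SD, n = 8) of the counts of vehicle livers and 3.89% ± 0.637 of those of bromobenzene livers, and the fallers 1.59% ± 0.159 and 0.947% ± 0.192. These shares describe transcripts picked by the same test. Among 413 liver-enriched transcripts, 20 rose, 9 fell and 384 did not pass, with a median log2 change of 0.02 (camera adjusted p = 0.343). Of 506 kidney-enriched transcripts tested, 6 rose and 1 fell (camera adjusted p = 0.343). Among 43 transcripts that rose in kidney at 5 h, 8 rose in liver too and none fell, with a median log2 change of 0.29 (camera adjusted p = 2.59e-11, and adjusted p = 0.00571 with an estimated correlation). Of 27 that fell in kidney, 1 rose and 1 fell in liver (camera adjusted p = 0.192). Membership of both kidney lists was unstable, since leaving out single libraries gave from 8 to 448 kidney calls at 5 h in place of 75. Livers and kidneys came from the same rats, so a list called in one organ can move in the other without a shared response, here and wherever such lists are compared below. The 488 calls became 758 without bromobenzene replicate 2 and 274 with only the 5 h groups fitted. The split turned to 194 higher and 241 lower when libraries were scaled by their totals alone, and to 177 and 258 with limma on log2(TPM + 1). With the run of library numbers as a covariate there were 435 calls. The first run alone (2 bromobenzene and 5 vehicle libraries) gave 0 with edgeR, with 956 at an unadjusted p under 0.05 and no other tool run, and the second run alone (6 and 3) gave 13.

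After 10 h the same liver comparison gave 1083 transcripts that rose and 884 that fell. Their median changes were 1.46-fold and 1.36-fold, with 208 and 103 changed at least 2-fold. The risers made up 4.29% ± 0.189 (SD, n = 8) of the counts in vehicle livers and 7.21% ± 0.897 in bromobenzene livers, and the fallers 14.1% ± 0.397 and 10.8% ± 0.43. ENSRNOT00000017181.4 had the largest rise, from 1.38 ± 0.536 CPM in vehicle livers to 48.96 ± 62.3 CPM in bromobenzene livers (n = 8 each). Its log2 change was 5.08 (SE 0.64, edgeR adjusted p = 2.82e-06), and from 3.06 to 5.36 over 50 alternatives. Single bromobenzene libraries ranged from 2.34 to 170.5 CPM, all above the highest vehicle library at 2.18. ENSRNOT00000010639.4 fell by 2.21 on the log2 scale (SE 0.35, edgeR adjusted p = 5.93e-05), from 202.4 ± 74.4 to 45.5 ± 15.8 CPM.

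**Figure D2:**
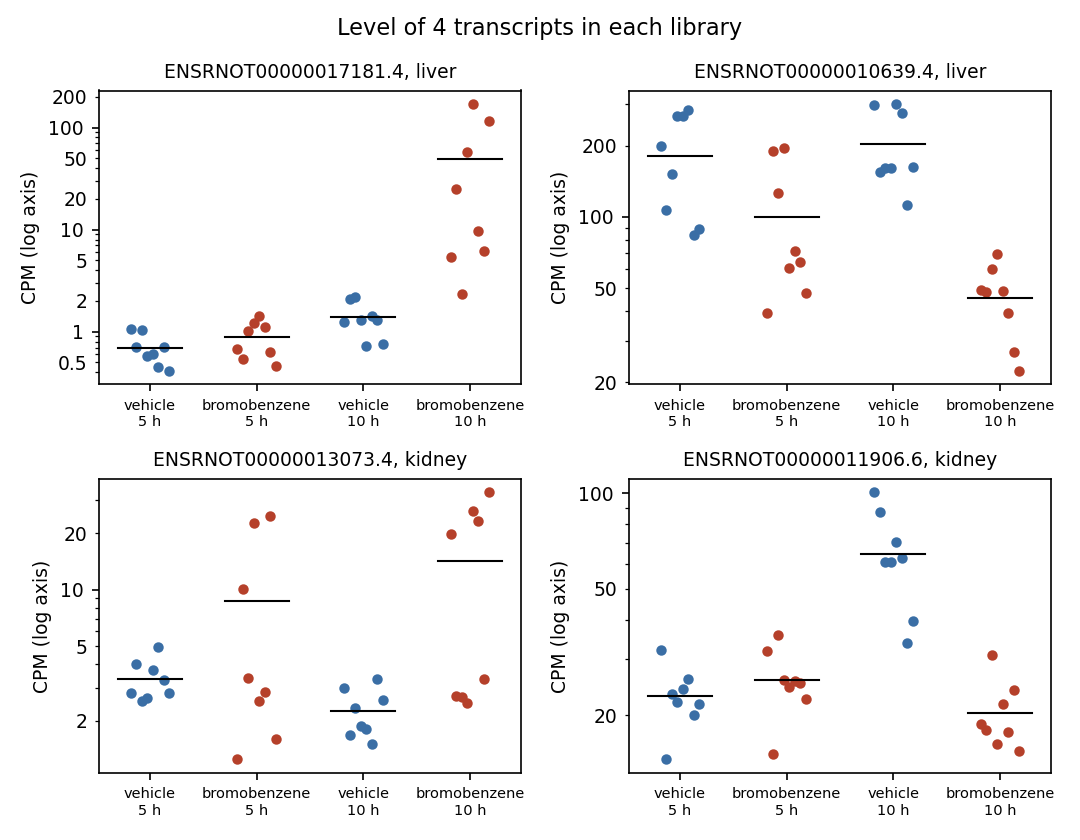
Level of each named transcript in every library of the tissue it was named in (vertical log axis, CPM; points are libraries, 8 per group; black lines are group means). ENSRNOT00000017181.4 ranged from 2.34 to 170.5 CPM in bromobenzene livers at 10 h, and ENSRNOT00000013073.4 from 2.49 to 33.05 CPM in bromobenzene kidneys at 10 h.

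More liver-enriched transcripts fell than rose at 10 h, and so did the most abundant liver transcripts in general. Of all tested transcripts with a mean of 100 CPM or more, 179 fell and 90 rose. Those at 20 to 100 CPM gave 352 and 373, and those at 5 to 20 CPM gave 223 and 399. Whether the falls below go with liver enrichment or with abundance was not tested. Of 396 liver-enriched transcripts, 47 fell, 18 rose and 331 did not pass, with a median log2 change of -0.10 against 0.01 for the rest. The median was -0.05 when scaled by totals alone (rest 0.07), -0.04 with limma on log2(TPM + 1) (rest 0.05) or log2(TPM + 0.1) (rest 0.07), and -0.12 in the first run alone (rest 0.03) and -0.04 in the second (rest 0.02). The camera adjusted p was 0.000114, but adjusted p = 0.149 with an estimated correlation, and the fry adjusted p was 0.00949. Their share of counts was 43.2% ± 1.85 (SD, n = 8) after bromobenzene and 44.9% ± 1.22 after vehicle (exact permutation p = 0.0458, adjusted over 8 shares 0.183). With single libraries left out the unadjusted exact p ran from 0.00979 (without bromobenzene replicate 7) to 0.0915 (without bromobenzene replicate 5), and it was above 0.05 without bromobenzene replicate 1, 2, 4, 5 or 8 or vehicle replicate 1, 3, 4, 6 or 8. Of 472 kidney-enriched transcripts tested in liver, 19 rose and 13 fell, with a median log2 change of 0.00 (camera adjusted p = 0.949). The kidney-enriched share of liver counts was 0.302% ± 0.107 after bromobenzene and 0.212% ± 0.0106 after vehicle (exact permutation p = 0.0042, adjusted 0.0336), and 5 transcripts made up 92.2% of that difference. Bromobenzene replicate 5 held 0.5235%, and without it the bromobenzene mean was 0.2706% and the difference went from 0.0906 to 0.059 percentage points (exact permutation p = 0.00466). The transcripts that rose in kidney at 10 h included 15 that rose and 1 that fell in liver, among 54 tested (camera adjusted p = 5.66e-05, and adjusted p = 0.0146 with an estimated correlation). Of 57 that fell in kidney, 15 fell and none rose in liver (camera adjusted p = 2.82e-07, and adjusted p = 0.000769 with an estimated correlation). Scaling by library totals alone moved the split of the 10 h calls to 1429 higher and 653 lower, and limma on log2(TPM + 1) to 1318 and 674. The run covariate gave 2002 calls, the first run alone (5 bromobenzene and 6 vehicle libraries) 871, and the second run alone (3 and 2) 3.

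Whether liver responded differently at the 2 times was tested as the difference between the contrasts. It passed for 607 transcripts, 330 with a more positive change at 10 h and 277 with a more negative one. ENSRNOT00000017181.4 was among them, with a log2 difference of 4.69 (SE 0.95, edgeR adjusted p = 0.00398). The change in ENSRNOT00000010639.4 did not differ by this test (log2 difference -1.40, SE 0.47, edgeR adjusted p = 0.103). Of 1811 transcripts called at 10 h only, 409 passed the test of the difference, and of 332 called at 5 h only, 116 passed. Calls at both times went the same way for 137 transcripts and opposite ways for 19, all 19 of which passed. The 69 shared risers compare with 16.61 for independent lists (Fisher's exact test, adjusted p = 4e-24), and the 68 shared fallers with 11.04 (adjusted p = 1.84e-34). Fisher's test takes transcripts as independent, which they are not, here and in the overlaps below. At 5 h 6.69% of transcripts at 100 CPM or more were called against 0.52% below 1 CPM. At 10 h these were 22.8% and 2.65%, so independent lists do not give the overlap expected without a shared response. As groups, the 1083 risers of 10 h had a median log2 change of 0.09 at 5 h (camera adjusted p = 3.35e-07, but adjusted p = 0.111 with an estimated correlation) and the 884 fallers -0.07 (6.47e-09, but adjusted p = 0.0756 with an estimated correlation). The 269 risers of 5 h had a median of 0.18 at 10 h (camera adjusted p = 2.82e-07, but adjusted p = 0.216 with an estimated correlation) and the 219 fallers -0.19 (2.73e-14, but adjusted p = 0.0502 with an estimated correlation). Liver-enriched transcripts gave 5 more positive and 16 more negative at 10 h among 381 (camera adjusted p = 0.000109, but adjusted p = 0.199 with an estimated correlation), and 439 kidney-enriched ones gave 5 and 5 (camera adjusted p = 0.339). The fry adjusted p was 0.0259 and 0.00739 for the risers and fallers of 10 h, and 0.0181 and 0.000352 for those of 5 h. For the liver-enriched transcripts the fry adjusted p was 0.0526. DESeq2 called 919 differences. Scaling by totals alone split its 682 calls as 505 more positive and 177 more negative, with the median of all transcripts moved to 0.10 on the log2 scale, and limma on log2(TPM + 1) gave 444 and 160. The run covariate gave 651, the first run alone 13, and the second run alone 0 with edgeR, with 1471 at an unadjusted p under 0.05 and no other tool run.

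In kidney at 5 h, 47 transcripts rose and 28 fell in bromobenzene rats, of 20004 tested. The risers changed by a median of 1.69-fold, 15 of them at least 2-fold, and the fallers by 1.24-fold, none at least 2-fold. The risers made up 0.146% ± 0.0208 (SD, n = 8) of the counts in vehicle kidneys and 0.244% ± 0.0604 in bromobenzene kidneys. Of 252 transcripts that rose in liver at 5 h, 8 rose and 1 fell in kidney (camera adjusted p = 8.69e-07, but adjusted p = 0.0872 with an estimated correlation). Of 213 that fell in liver, 1 fell and none rose (camera adjusted p = 0.00215, but adjusted p = 0.0872 with an estimated correlation). The fry adjusted p was 0.0146 for both lists. Among 238 liver-enriched transcripts tested in kidney, edgeR called 0 and DESeq2 called 2, with 88 at an unadjusted p under 0.05, and their median log2 change was -0.53 (camera adjusted p = 9.07e-06, but adjusted p = 0.42 with an estimated correlation and fry adjusted p = 0.303). Vehicle replicate 4 held 2.09% of its counts in liver-enriched transcripts, against 0.250% to 0.334% in the other vehicle kidneys at 5 h. Without it and bromobenzene replicate 8, which had the fewest detected transcripts, the median was 0.24. Without bromobenzene replicate 1 as well, which held 0.562%, it was -0.05. The median was -0.79 in the first run alone, which holds vehicle replicate 4, and -0.02 in the second. Its sign and size therefore rested on a few libraries. Of 905 kidney-enriched transcripts, 2 rose and 6 fell (camera adjusted p = 0.19).

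**Figure D3:**
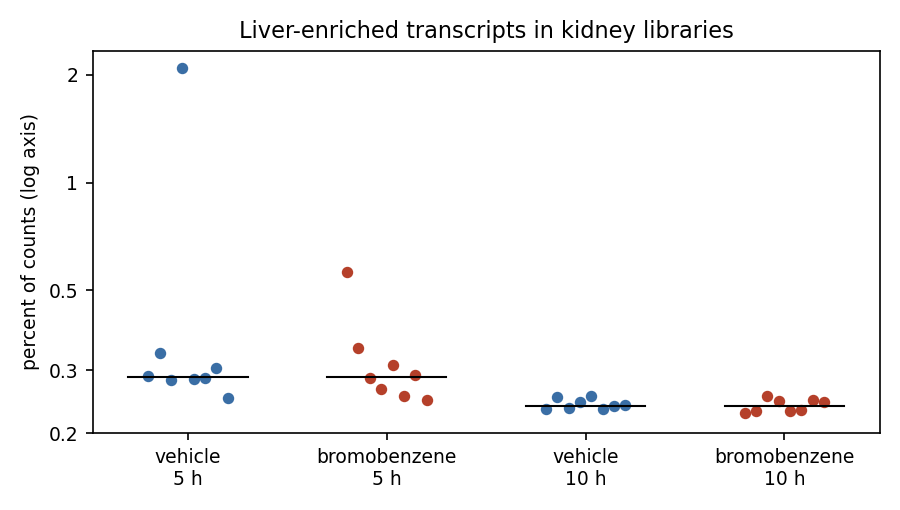
Share of each kidney library's estimated counts in liver-enriched transcripts (vertical log axis, percent; 413 transcripts for 5 h and another list of 396 for 10 h; points are libraries, 8 per group; black lines are group medians). Vehicle replicate 4 at 5 h stands at 2.09% and bromobenzene replicate 1 at 5 h at 0.562%.

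The count of 75 in kidney at 5 h rested on single libraries. Left out one at a time, the following 5 h vehicle libraries gave 25 (replicate 1), 8 (replicate 2), 29 (replicate 3), 13 (replicate 4), 38 (replicate 7) and 298 (replicate 8) calls. The 5 h bromobenzene libraries gave 161 (replicate 2), 25 (replicate 3), 10 (replicate 5), 16 (replicate 7) and 448 (replicate 8). Removal of a single 10 h library, which is outside this contrast but in the shared fit, gave 42 to 49 calls for vehicle replicates 1, 2, 6 and 7 and bromobenzene replicates 2, 3, 4 and 6. Without vehicle replicate 4 and bromobenzene replicate 8 together, 198 rose and 162 fell. DESeq2 called 384, and a fit of the 5 h groups alone called 0 with edgeR, with 1962 at an unadjusted p under 0.05. Scaling by totals alone gave 74 higher and 15 lower, and limma on log2(TPM + 0.1) 24 and 7. The run covariate gave 71 calls, the first run alone (2 bromobenzene and 5 vehicle libraries) 5, and the second run alone (6 and 3) 0 with edgeR, with 1070 at an unadjusted p under 0.05.

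After 10 h, 61 kidney transcripts rose and 64 fell. Their median changes were 1.31-fold and 1.27-fold, with 10 and 2 changed at least 2-fold. The risers made up 0.733% ± 0.0245 (SD, n = 8) of the counts in vehicle kidneys and 0.949% ± 0.062 in bromobenzene kidneys, and the fallers 0.480% ± 0.0149 and 0.3645% ± 0.0117. ENSRNOT00000013073.4 had the largest rise among those named by the rule, 2.67 on the log2 scale (SE 0.61, edgeR adjusted p = 0.0296). It stood at 14.2 ± 12.7 CPM in bromobenzene kidneys, with single libraries from 2.49 to 33.05, and at 2.26 ± 0.66 CPM in vehicle kidneys (n = 8 each). Bromobenzene replicates 2, 3, 4 and 7 stood at 2.71, 2.68, 2.49 and 3.34 CPM, within or close to the vehicle range, whose highest library was 3.32. Replicates 1, 5, 6 and 8 stood at 19.78 to 33.05 CPM. The call ended in 18 of 52 alternatives, with an adjusted p from 0.000558 to 1 over all of them and a log2 change from 1.70 to 2.84. The same transcript rose in liver at 10 h by 2.91 (SE 0.58, edgeR adjusted p = 0.000877). It stood at 2.17 ± 1.61 CPM in bromobenzene livers, with single libraries from 0.167 to 4.505, and at 0.271 ± 0.158 CPM in vehicle livers. In those vehicle libraries 3 counts make 0.121 to 0.17 CPM, so the rise starts from few counts. ENSRNOT00000011906.6 fell by 1.63 (SE 0.19, edgeR adjusted p = 1.55e-05), from 64.5 ± 22.2 to 20.4 ± 5.16 CPM. Over 52 alternatives this transcript had a log2 change from -1.77 to -0.94. In vehicle kidneys it had risen between 5 h and 10 h by 1.46 (SE 0.19, edgeR adjusted p = 9e-06), a comparison that shares the same 10 h vehicle libraries.

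The transcripts called in liver at 10 h were also examined in kidney. Of 1071 transcripts that rose in liver at 10 h, 15 rose and none fell in kidney, with a median log2 change of 0.04 (camera adjusted p = 1.26e-05, and adjusted p = 0.00107 with an estimated correlation). Of 860 that fell in liver, 15 fell and 1 rose in kidney, with a median of -0.03 (camera adjusted p = 1.26e-05, and adjusted p = 0.0193 with an estimated correlation). Independent lists would share 3.42 risers and 2.9 fallers, but the lists come from organs of the same rats, so these are not the values expected without a shared response. Of 223 liver-enriched transcripts, edgeR and DESeq2 called 0, with 7 at an unadjusted p under 0.05 (camera adjusted p = 0.394). Of 849 kidney-enriched transcripts, 7 rose and 17 fell (camera adjusted p = 0.32), and their share of counts was 14.1% ± 0.238 (SD, n = 8) after bromobenzene and 14.3% ± 0.24 after vehicle (exact permutation p = 0.0946, adjusted 0.252, but unadjusted 0.0236 without bromobenzene replicate 4 and 0.0168 without vehicle replicate 8). The 125 calls became 79 without 10 h vehicle replicate 5, 83 without 10 h bromobenzene replicate 1, 332 with DESeq2, 357 with voom and sample weights, 234 with only the 10 h groups and 225 with the length trend as a covariate. Scaling by totals alone split the calls as 55 higher and 142 lower, and limma on log2(TPM + 1) as 38 and 181. The run covariate gave 169 calls, the first run alone (5 bromobenzene and 6 vehicle libraries) 37, and the second run alone (3 and 2) 0 with edgeR, with 798 at an unadjusted p under 0.05 and no other tool run.

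The kidney response differed between the times for 27 transcripts, 12 with a more positive change at 10 h and 15 with a more negative one. ENSRNOT00000011906.6 was among the latter, with a log2 difference of -1.78 (SE 0.27, edgeR adjusted p = 0.00256). Of 123 transcripts called in kidney at 10 h only, 13 passed the test of the difference, and of 73 called at 5 h only, 6 passed. Both times shared 2 fallers (0.09 for independent lists, Fisher's exact test adjusted p = 0.00902) and 0 risers, among 47 and 61. Of the 61 risers of 10 h, edgeR called 0 and DESeq2 called 3 at 5 h, with 14 at an unadjusted p under 0.05 (camera adjusted p = 0.003, but adjusted p = 0.161 with an estimated correlation). Of the 64 fallers, 2 fell at 5 h (camera adjusted p = 8.69e-07, but adjusted p = 0.0522 with an estimated correlation). Of the 47 risers of 5 h, edgeR and DESeq2 called 0 at 10 h, with 9 at an unadjusted p under 0.05 (camera adjusted p = 0.394), and of the 28 fallers 2 fell (camera adjusted p = 1.95e-05, but adjusted p = 0.134 with an estimated correlation). The fry adjusted p was 0.0472 and 0.00359 for the risers and fallers of 10 h, and 0.833 and 0.0451 for those of 5 h. In the difference between the times, edgeR and DESeq2 called 0 of 215 liver-enriched transcripts, with 18 at an unadjusted p under 0.05 (camera adjusted p = 9.01e-07, but adjusted p = 0.75 with an estimated correlation and fry adjusted p = 0.631), a contrast that includes 5 h vehicle replicate 4. Of 801 kidney-enriched ones, 3 were more positive and 2 more negative (camera adjusted p = 0.699). The count was 13 without 5 h vehicle replicate 4 or 10 h bromobenzene replicate 1. It was 15 to 17 without 5 h vehicle replicate 2 or 3, 5 h bromobenzene replicate 3 or 5, 10 h vehicle replicate 5, 6 or 7, or 10 h bromobenzene replicate 6 or 8. It was 51 without 5 h vehicle replicate 8, 86 without 5 h bromobenzene replicate 8, and 145 with DESeq2. Scaling by totals alone split 45 calls as 7 and 38, and limma on log2(TPM + 1) split 34 as 3 and 31. The run covariate gave 36, the first run alone 7, and the second run alone 0 with edgeR, with 822 at an unadjusted p under 0.05.

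A response score measured each library on transcripts called in other rats, those sampled at the other time. Each tissue and time therefore had its own list, so score sizes do not compare between times or organs. Bromobenzene livers scored 0.252 ± 0.093 (SD, n = 8) at 5 h and 0.531 ± 0.195 at 10 h, in log2 units above the vehicle mean of 0. At each time 7 of 8 bromobenzene livers lay above the highest vehicle liver (exact permutation p = 0.000311, adjusted over 4 scores 0.000415). Bromobenzene kidneys scored 0.201 ± 0.141 at 5 h (exact permutation p = 0.000311, adjusted 0.000415), with 7 of 8 above the highest vehicle kidney. At 10 h they scored 0.137 ± 0.166, again with 7 of 8 above, but replicate 7 lay at -0.214 and the test did not pass (exact permutation p = 0.0626). The 10 h kidney score uses the 5 h kidney calls, whose count ran from 8 to 448 with single libraries left out. It therefore rests on an unstable list. Without bromobenzene replicate 7 the mean difference was 0.187 (exact permutation p = 0.000155, the smallest these splits can give). That p follows from removing the only bromobenzene kidney not above every vehicle kidney, so it is no separate support. With any other single library left out, the exact permutation p ran from 0.0597 to 0.127. The differences in liver were 0.28 and 0.195 within the first and second runs at 5 h, and 0.542 and 0.545 at 10 h. In kidney they were 0.192 and 0.193 at 5 h, and 0.167 and 0.113 at 10 h.

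**Figure D4:**
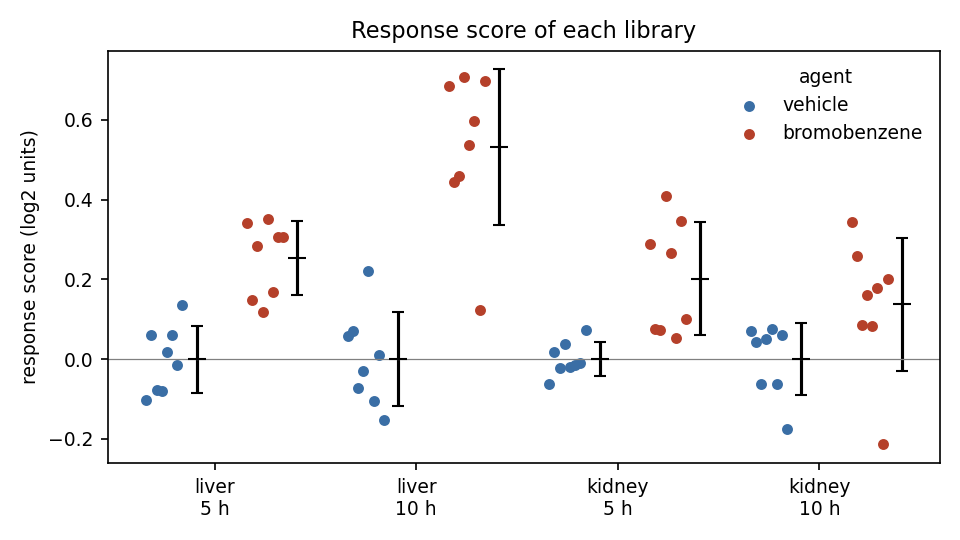
Response score of each library (vertical axis, log2 units; points are libraries, 8 per group; black marks are means with SD bars). Of 8 bromobenzene libraries, 7 lie above the highest vehicle library in each tissue and time. Each tissue and time is scored on its own list of transcripts, so heights do not compare between them.

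The organs were compared directly over transcripts measured in both. At 5 h, 151 of 14128 transcripts responded differently, 95 with a more positive change in liver and 56 with a more negative one. At 10 h, 1131 of 14008 did, 602 and 529. ENSRNOT00000017181.4 changed more in liver than in kidney at 10 h (log2 difference 4.76, edgeR adjusted p = 0.000318), while for ENSRNOT00000013073.4 the difference was 0.25 (adjusted p = 0.902). At 5 h the count was 89 without liver bromobenzene replicate 5, 91 without kidney vehicle replicate 2, 371 without liver bromobenzene replicate 2 and 373 with DESeq2, and it was 124 (59 and 65) without kidney vehicle replicate 4 and bromobenzene replicate 8. At 10 h it was 1971 without liver bromobenzene replicate 3. Scaling by totals alone gave 50 more positive and 73 more negative at 5 h and 1095 and 308 at 10 h, and limma on log2(TPM + 1) gave 32 and 53 and 1182 and 266. With the run covariate the counts were 167 and 1183. Liver and kidney libraries were taken as independent although they came from the same 32 rats.

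The vehicle groups gave the background of the 2 collection times. In vehicle livers, 758 transcripts were higher and 876 lower at 10 h than at 5 h, with median changes of 1.41-fold and 1.49-fold. In vehicle kidneys, 576 were higher and 561 lower, by 1.3-fold and 1.26-fold. Both organs shared 117 transcripts that were higher at 10 h, against 23.38 for independent lists (Fisher's exact test, adjusted p = 9.52e-49), and 85 that were lower, against 25.63 (adjusted p = 2.43e-22). Opposite directions were shared by 16 and 14 transcripts, against 22.33 and 26.84. The organs of one rat share its deviations, so independent lists do not give the overlap expected without a shared drift. Of 744 transcripts that rose in vehicle livers, the median log2 change in kidney was 0.06 (camera adjusted p = 3.33e-10, and adjusted p = 0.00224 with an estimated correlation), and of 854 that fell it was -0.06 (camera adjusted p = 1.48e-06, and adjusted p = 0.00115 with an estimated correlation). In liver, the 531 that rose in vehicle kidneys had a median of 0.11 (camera adjusted p = 2.23e-12, but adjusted p = 0.0642 with an estimated correlation) and the 507 that fell -0.08 (1.41e-06, but adjusted p = 0.0642 with an estimated correlation). For these 2 lists the fry adjusted p was 0.00231 and 0.00098. The kidney count fell from 1137 to 514 with the length trend as a covariate. Its split was 825 higher and 385 lower when scaled by totals alone and 1231 and 192 with limma on log2(TPM + 1). Voom with sample weights called 2618 in liver. Within the first run (6 vehicle libraries at 10 h and 5 at 5 h) the counts were 701 in liver and 946 in kidney, and within the second run (2 and 3) 116 and 14, against 1635 and 1203 with the run covariate.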

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

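Tests chosen only after the result was seen were both tests of the liver-enriched signal in kidney vehicle replicate 4, the test for liver RNA in kidney bromobenzene replicate 8, and the counts with libraries removed. Over 80 sets of 8 libraries compared, 9 had a library set apart from the others by a gap test that chance passes in about 5% of sets, so a few of these values are within chance.

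Kidney vehicle replicate 4 at 5 h held 2.086% of its counts in liver-enriched transcripts, far above the other vehicle kidneys, and 9.484 CPM of ENSRNOT00000010639.4, a transcript abundant in liver. Of 413 liver-enriched transcripts, 86.4% were higher in this library than in each of 31 other kidney libraries, among them 47 of the 50 most abundant in liver, and the excess had a median of 3.73% of the level in liver (interquartile range 3.04% to 4.33%). Exchanged liver and kidney labels are argued against by its kidney-enriched share of 13.24%, within the other kidneys' 12.87% to 14.23% and far from the highest liver at 0.27%, with the 5 h list of 905 transcripts applied to all libraries. A small amount of liver RNA or liver reads may account for the signal, and whether it entered at dissection, library preparation or sequencing stays open. No biological explanation was tested, since the design gives none for a single rat.

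Kidney bromobenzene replicate 8 at 5 h had 21251 detected transcripts, set apart below the other bromobenzene kidneys at 5 h, and 45 transcripts lay more than 1.5 log2 units below every other kidney, against 4 in the next library. Depth is argued against, since each other kidney library, thinned to its total where deeper, kept at least 22590. Liver RNA is argued against by a liver-enriched share of 0.2468%, the lowest of 16 kidneys at 5 h (the others 0.2504% or more, median 0.2881%). A stronger response is argued against by a response score of 0.101, the fifth of 8. A fault of quantification or of the library may remain, and this was not tested. Of its estimates 34.05% were fractional, against 38.11% to 40.17% in the other kidneys. Undetected transcripts count as whole in that share, so it is not separate from the low number detected.

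Transcripts that rose over time in vehicle kidneys were more often lower than higher in bromobenzene livers at 10 h, with 47 lower (27 for independent lists) and 23 higher (33.7), a pattern found by comparing lists. Length trends between libraries are argued against, because with that trend as a covariate in both fits the odds ratio for being lower was 3.62 (95% interval 2.5 to 5.15). Vehicle rats shared by the organs would raise this overlap by chance, and the test replaced vehicle kidneys by bromobenzene kidneys. The odds ratio for being lower was then 2.09 (Fisher's exact p = 0.000479), which met the bound written beforehand against this explanation, but that bound was wrong because the odds ratio for being higher rose too, to 2.24, so the test does not separate the directions. Shared vehicle rats therefore cannot be told apart from a response of liver to bromobenzene that runs against the drift between collection times, which may also contribute.

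Other values set apart were these. The response score of liver bromobenzene replicate 7 at 10 h was 0.123, the lowest of its group, and that of kidney bromobenzene replicate 7 at 10 h was -0.214, also the lowest of its group. These are libraries 26 and 58, which would be one rat if library n and library n + 32 are a pair, so they would not be separate observations, and why they scored low was not tested. The liver-enriched share of liver vehicle replicate 3 at 10 h was 47.53%, the highest of its group. Kidney bromobenzene replicate 1 at 5 h held 0.5625% of its counts in liver-enriched transcripts and 1.051 CPM of ENSRNOT00000010639.4. Liver bromobenzene replicate 1 at 10 h held 1.741 CPM of ENSRNOT00000011906.6.

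Responses differed between the times for 607 transcripts in liver and 27 in kidney, and between the organs for 151 at 5 h and 1131 at 10 h, by tests of the difference itself. Each count was set against 50 splits of the same libraries into groups of the same sizes, the real one included. For the 607, 1 of 50 splits called as many (highest other 66), for the 27, 1 (highest other 1), and for the 151, 1 (highest other 1). For the 1131, 2 of 50 did, and the other one called 2105. Each share is under 0.05. But agent labels were shuffled within each time or organ, so the other splits stand for no treatment effect at all. They do not show what equal responses at both times or in both organs would give, so they cannot exclude chance for these differences. Why 1 split called 2105 was not tested. Among the remaining counts, 1 of 50 splits was as large for liver at 5 h (488, highest other 3) and liver at 10 h (1967, highest other 4). The same held for kidney at 10 h (125, highest other 4), vehicle liver over time (1634, highest other 379) and vehicle kidney over time (1137, highest other 0). These shares are under 0.05 and argue against chance. The real split is 1 of the 50, so no smaller share could be reached, and chance is not excluded. For kidney at 5 h, 3 of 50 splits called at least the 75 of the real one, with 85 the highest. That share is above 0.05, so the splits do not argue against chance there.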

How the results depend on the processing

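Each library left out, both covariates, the separate runs and the removal of libraries that stood apart were chosen only after the data were seen. Of 126 counts under the alternatives fixed beforehand, 82 stayed within 1.5 times the reported count, and RLE factors, the effective length offset and removal of the 20 most abundant transcripts kept every count they gave within it. The cause of the moves below was not tested except where named.

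A 1.5-fold minimum asks for more than the test of no change, and left 33 and 99 calls in liver at 5 h and 10 h, 30 between the times and 194 in vehicle liver. In kidney it left 0 (edgeR, 216 at an unadjusted p under 0.05), 1, 0 (147) and 25, and between organs 5 at 5 h and 42 at 10 h. An adjusted p under 0.01 is stricter by construction and left 226, 973, 227 and 869 in liver, 0 (2805 at an unadjusted p under 0.05, DESeq2 384 at 0.05), 43, 7 and 426 in kidney, and 37 and 478 between organs.

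DESeq2 called 919 between the times in liver, 384, 332 and 145 in kidney at 5 h, 10 h and between the times, and 373 between organs at 5 h. Voom with sample weights called 2618 in vehicle liver and 158, 357 and 62 in kidney at 5 h, 10 h and between the times. Fits of only the groups compared gave 274 in liver at 5 h, and 0 (1962 at an unadjusted p under 0.05) and 234 in kidney at 5 h and 10 h. Scaling by totals alone gave 197 in kidney at 10 h and 45 between its times. With no filter on low counts there were 43 in kidney at 5 h and 83 between organs at 5 h, and with a mean CPM of at least 5 there were 131 in kidney at 5 h and 43 between its times. Limma gave 25 in kidney at 5 h, 219 at 10 h and 85 between organs at 5 h on log2(TPM + 1), and 31, 215 and 81 on log2(TPM + 0.1). For the difference between the times in liver, the median of all transcripts was 0.10 by totals alone and 0.12 on log2(TPM + 0.1). It was 0.009 in the main fit. Between organs at 10 h the median was 0.11 on log2(TPM + 0.1), against 0.005 in the main fit.

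The run covariate moved none of the 10 counts past 1.5 times. Fewer libraries enter the first run alone, which gave 0 (956 at an unadjusted p under 0.05), 871, 13 and 701 in liver and 5, 37 and 7 in kidney at 5 h, 10 h and between its times, or the second run alone, which gave 13, 3, 0 (1471) and 116 in liver and 0 (1070), 0 (798), 0 (822) and 14 in kidney. The length covariate gave 225 in kidney at 10 h, 55 between its times and 514 in its vehicle comparison. Without the 2 kidneys of steepest length trend there were 8 at 5 h, 12 between the times and 537 in the vehicle comparison. Without kidney vehicle 4 and bromobenzene 8 at 5 h, kidney had 360 at 5 h and 57 between the times, and without bromobenzene 1 as well, 284 and 73.

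With single libraries left out, counts ran from 339 to 758 in liver at 5 h, 1480 to 2609 at 10 h, 465 to 865 between its times and 1348 to 1781 in vehicle liver. They ran from 8 to 448 in kidney at 5 h, 79 to 179 at 10 h, 13 to 86 between its times and 775 to 1457 in vehicle kidney, and from 89 to 371 and 930 to 1971 between organs. The named transcripts kept their direction in each alternative, and ENSRNOT00000013073.4 lost its call in 18 of 52, against 1 of 50 or 52 for the others, where the second run alone left 3 against 2 libraries.

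The labels do not pair liver and kidney libraries. Taking liver library n and kidney library n + 32 as one rat, with voom and limma, gave 141 and 1440 calls between organs. The edgeR fits without the pairs gave 151 and 1131. The tool changed along with the pairing, so the moves cannot be credited to the pairs. The fitted correlation within pairs was 0.046 at 5 h and 0.101 at 10 h. Such libraries deviated from their groups together with a mean correlation of 0.173, against 0.027 when shuffled within group and run (permutation p = 1e-05, the smallest that 100000 shuffles can give). Of 32 kidneys, 24 were the best match within group and run (8 by chance), and 24 of 32 correlations were over 0.1, so the pairing is a hint from the data and the shared run alone is argued against. Of 31715 transcripts, 17535 in liver and 20004 in kidney had enough counts to be tested. Simulated 1.5-fold changes at 10 h were recovered at 57.5% in liver and 78.8% in kidney, in transcripts above a minimum mean count. The simulation did not vary depth, and liver was the deeper tissue and had the larger spread (common biological coefficient of variation 0.307 against 0.259).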

Other observations

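The overlaps and the correlations of scores in this part were chosen after the data were seen.

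Lists of transcripts that fell between 5 h and 10 h in vehicle animals of one organ were set against the 10 h calls of the other organ, and most of their members were not called there. Of 507 transcripts that fell over time in vehicle kidneys, 62 were higher in bromobenzene livers at 10 h against 32.1 for independent lists (odds ratio 2.12, Fisher's exact p = 6.32e-07), and 33 were lower against 25.8 (odds ratio 1.31, Fisher's exact p = 0.15). With the list taken from bromobenzene kidneys in place of vehicle kidneys, 23 of 298 were higher against 18.9 (odds ratio 1.24, Fisher's exact p = 0.336) and 36 were lower against 15.2 (odds ratio 2.63, Fisher's exact p = 1.5e-06), so the direction in excess turned with the rats that defined the list. Of 854 that fell over time in vehicle livers, 14 were higher in bromobenzene kidneys at 10 h against 2.7 (odds ratio 6.66, Fisher's exact p = 3.13e-07), and 1 was lower against 2.9. No list from bromobenzene livers was set against kidney. All lists were drawn from organs of the same rats, so independent lists do not give the overlap expected without a response, and these overlaps are 6 of 16 computed.

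Response scores were set against each other between liver library n and kidney library n + 32, a pairing the labels do not state. In the 10 h vehicle group Pearson's r was 0.81 (exact permutation p = 0.0142, adjusted over 4 groups 0.0554) and Spearman's rho 0.85 (exact permutation p = 0.0114, adjusted 0.0456), and r was 0.84 without the 2 libraries farthest from the median and 0.80 (rho 0.81) among the 6 pairs of the first run. In the 10 h bromobenzene group r was 0.82 (exact permutation p = 0.0277, adjusted 0.0554) and rho 0.41 (exact permutation p = 0.327, adjusted 0.436), and r fell to 0.46 without those 2, so it rests on them, and was 0.36 (rho 0.10) among the 5 pairs of the first run. At 5 h with vehicle r was 0.60 (exact permutation p = 0.114), -0.20 without the 2 farthest libraries and 0.35 (rho 0.40) among the 5 pairs of the first run, and rho 0.57 (exact permutation p = 0.151). At 5 h with bromobenzene r was 0.11 (exact permutation p = 0.815) and rho 0.17 (exact permutation p = 0.703). There r was 0.68 without the 2 farthest libraries and -0.15 (rho 0.09) among the 6 pairs of the second run.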
